A study of Rattus norvegicus with 18 samples.

How the data were processed

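Hypothalamic RNA from 18 male Wistar rats was hybridised to 1-colour rat arrays, 1 array per rat, with 6 rats in each of 3 groups. Per the labels, RNA integrity numbers lay above 7 and absorbance ratios above 1.7. The labels give 100 ng of RNA in the extraction text and 200 ng in the labelling text, and which was used stays open. Each array file holds 62976 spots, of which 58717 are not controls and belong to 45598 probes.

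The intensity used here is the processed signal of each spot, which Agilent Feature Extraction had already corrected for background and spatial trend, per the file headers. The headers name version 12.1.0.3 of that program and the submitters' processing notes name 9.1; the header version was written by the program itself. The values of the authors' series matrix were set against the scanner values of the same arrays. On each array the matrix intensity was the processed signal times 1 constant, between 1.02 and 1.24 over the arrays, with a largest relative range within an array of 9.96e-10. The matrix is therefore linear and not centred by gene, and column medians ran from 156.67 to 176.491. How the authors chose the constant is not given in the sources used here.

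Values were computed as log2 of the processed signal minus the array's own 75th percentile over all probes that are not controls. A level of 0 is thus the 75th percentile of that array, and levels are not comparable between probes. Outlier spots (297 to 580 per array) and control spots were left out, and spots of 1 probe were averaged. No spot was saturated. A probe was tested if it was well above background on at least 5 of the 6 arrays of at least 1 group, which kept 31299 probes. Probes were named only through their transcript accession in a table of rat genes of assembly GRCr8. The arrays were designed on build rn4, so no positions are given. Of the 45598 probes, 21220 matched 1 symbol, 0 matched several and 24378 matched none. The tested probes hold 16684 with a name, for 13055 genes. A gene with several tested probes is represented by the brightest of them.

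The 3 comparisons were tested with limma (lmFit and eBayes) on all 18 arrays with group as the only term. A probe counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes of that comparison, and p-values are two-sided. Standard errors are those of the moderated fit, and group spreads are standard deviations over 6 rats. A probe that was not well above background on any array of a group has only a bound there. For such probes the fold is given as at least the bright group's mean over the dim group's floor, the floor on each array being the higher of the lowest signal well above background and the probe's own value.

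A total of 31 gene lists were fixed with the tests, before the data were examined. The 16 function lists cover neuropeptides and receptors of the stress axis, glucocorticoid-responsive genes, feeding and energy balance, the angiotensin and vascular system, cytokines and chemokines, interferon and antigen presentation, immediate early genes, the clock, growth factors tied to exercise, heat shock and endoplasmic reticulum stress, antioxidant defence, monoamines, glutamate and GABA, oxidative phosphorylation, ribosomal proteins and cholesterol synthesis. The 15 cell and tissue lists cover microglia, perivascular macrophages and leukocytes, astrocytes, oligodendrocytes, their precursors, endothelium, mural cells and fibroblasts, ependyma and tanycytes, choroid plexus, pituitary, thalamus, striatum, cortex and hippocampus, hypothalamic neurons and erythrocytes. In the feeding list the symbol Sf1, meant for the nuclear receptor, matched splicing factor 1. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The mean of each list per rat was compared with an exact permutation test over all 924 arrangements of 6 against 6, whose smallest p is 0.00216, adjusted within the function lists and within the cell lists.

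The genes named were set by a rule fixed in the same way. For each comparison it takes the 12 largest changes per direction among genes that passed, or the 8 genes per direction with the smallest p where none passed. It adds up to 4 passing members per function list, or 2 with the smallest p where none passed, and in every case Crh, Avp, Oxt, Pomc, Npy, Agrp, Nr3c1, Fkbp5, Sgk1 and Fos. Not every gene under the rule is printed, and some are not reported here.

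File headers give 5 slides and 2 scan days. Slides 1 to 3 held the 6 control arrays and stress arrays 1 to 4, and slides 4 and 5 held stress arrays 5 and 6 and the 6 arrays of stress with exercise. Control arrays lay on slides 1 and 2 and stress arrays on slides 3 and 4, so no slide held both. Scan day was fitted as a block, slide as a random block through duplicateCorrelation, and slides 1 to 3 against slides 4 and 5 (the slide set) as a covariate; the last was added after the values were seen. Control and stress with exercise share no slide set, so that comparison with the covariate rests on the stress arrays lying in both.

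Other settings tried were normexp with an offset of 50 and quantile normalization, quantile normalization alone, no scaling, the series matrix, no filter on dim probes, probes well above background on all 18 arrays, 1 probe per gene, only the 2 groups compared, an intensity trend with robust hyperparameters, array weights, an adjusted p under 0.10, replicate number as a block, dissection covariates (the thalamic and striatal list means), and leaving out each array in turn. The files hold no column of mean spot signal, so normexp used the median signal and median background. All sample files were used.

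The fits were tested on simulated data with the spread of the 31114 probes measured on all arrays and 200 changed probes. With group as the only term, 62.8% of changes of 0.5 log2 were recovered for stress against control, 60.6% for stress with exercise against stress and 63.2% for stress with exercise against control. With the slide set as a covariate the shares were 58.4%, 44.8% and 30.6%. A simulated slide effect with an SD of 0.3 log2 and no group effect gave on average 0, 5774 and 13260 called probes in the same order. A list of 23 genes shifted by 0.3 log2 between control and stress with exercise was called in 20 of 20 runs over 13055 genes. With no shift, 1 of 20 runs called a list. Genes were drawn independently there, while the list used, antioxidant defence, had an estimated correlation of 0.111 and an observed difference of 0.10. The share called thus does not carry over to the measured lists. The direction test over 13055 genes gave a mean correlation of 0.03 with no effect, -0.57 with opposite effects, 0.60 with equal ones and 0.32 with the slide effect alone. The number of arrays per group limits the precision of every value.

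R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used for the tests, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for reading the files and drawing.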

Results

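RNA was measured in the hypothalamus of 18 male Wistar rats aged 9 weeks, with 1 array per rat. Control rats (n = 6) had neither restraint nor a wheel. Stress rats (n = 6) were held in restraint for 1 to 1.5 h a day on 5 days a week over 3 weeks. Rats with stress and exercise (n = 6) had the same restraint and a running wheel for 4 weeks, beginning 1 week before the restraint. By its title, the series asks how exercise acts on the brain and the bone marrow in hypertension brought on by chronic stress. Between 63.6% and 77.8% of 45598 probes were well above background on each array, and the 75th percentile of intensity ran from 423 to 528. Levels are log2 values relative to that percentile.

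The arrays lay on 5 slides. The first principal component held 31.8% of the variance and placed the 10 arrays of slides 1 to 3 (control 1 to 6 and stress 1 to 4) between 20.7 and 32.0, and the 8 arrays of slides 4 and 5 (stress 5 and 6 and all arrays of stress with exercise) between -39.2 and -25.7. Stress rats 5 and 6 thus lay with the exercised rats and apart from the other stress rats. The subunit Cox7c of cytochrome oxidase was at 2.24 and 2.40 in stress 5 and 6, against 3.21 to 3.31 in stress 1 to 4 and a mean of 2.27 ± 0.07 (SD, n = 6) with exercise. Between the stress arrays of slide 4 and those of slide 3, 3040 probes passed the test, 507 higher and 2533 lower on slide 4.

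**Figure D1:**
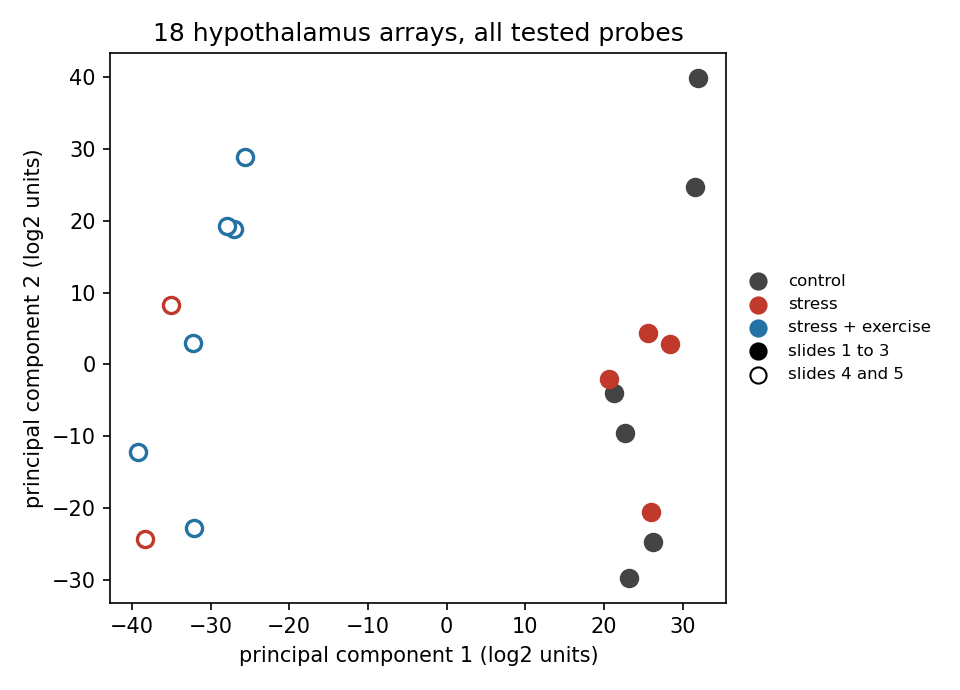
Each point is 1 array, placed by its scores on the first component (x axis, 31.8% of variance) and the second (y axis, 14.9%), computed over 31114 probes measured on all arrays; colours give the group, filled points slides 1 to 3 and open points slides 4 and 5. The 10 filled points lie between 20.7 and 32.0 on the x axis and the 8 open points between -39.2 and -25.7.

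The comparison of stress with control asks what 3 weeks of restraint left in the hypothalamus. Oxt, the gene of oxytocin, had a level of 5.21 ± 0.06 in control and 5.58 ± 0.22 in stress (SD, n = 6 each), a difference of 0.36 (SE 0.09). Crh, which encodes the releasing hormone at the head of the stress axis, was at 0.87 ± 0.16 and 1.19 ± 0.17, a difference of 0.32 (SE 0.10). The inducible chaperone gene Hspa1a differed by 0.37 (SE 0.09). All 6 stress rats lay above the control mean for each of these 3 genes, yet none passed the test over all probes, with adjusted p of 0.236 for Oxt, 0.273 for Crh and 0.236 for Hspa1a. With limma, 0 of 31299 probes changed between stress and control, where 3754 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0908.

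Adjusted over the list alone, 4 of 22 neuropeptide and receptor genes of the stress axis were higher in stress, against 0 over all probes: Crh, Oxt, Pdyn (dynorphin precursor, difference 0.17) and Adcyap1r1 (the PACAP receptor, difference 0.16). Over the 10 genes named in every comparison, the adjusted p was 0.00882 for Oxt and 0.0192 for Crh. Both became 0.0250 with the slide set as a covariate, where Oxt differed by 0.36 and Crh by 0.35. No slide held both control and stress arrays, so this does not part restraint from differences between single slides. Of the 10 genes the other 8 did not pass. They were Avp (0.13), Pomc (0.21), Npy (0.20), Agrp (0.16), Fos (0.31), the glucocorticoid receptor gene Nr3c1 (-0.04) and its targets Fkbp5 (0.04) and Sgk1 (0.04). Another probe of Nr3c1 was at -0.29 and did not pass over all probes (adjusted p = 0.236). Of 17 clock genes 2 were higher when adjusted over the list alone, Per1 (0.26) and Dbp (0.21), though another probe of Per1 was at -0.14. So was Hspa1a among 21 heat shock and endoplasmic reticulum genes, and over all probes the count was 0 for both lists. The counts adjusted over the list alone with the slide set as a covariate were 0 for the stress axis, 0 for the clock and 2 for heat shock (Hspa1a and Xbp1). In the remaining 13 function lists no gene passed either adjustment by limma.

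Among the genes with small p-values, those higher in stress included Msantd1 (0.36, adjusted p = 0.0908), the microtubule-binding protein gene Jakmip3 (0.24), the synaptic vesicle gene Rab3b (0.24), Neto1, an auxiliary subunit of glutamate receptors (0.19), and the glucokinase gene Adpgk (0.36). B3gntl1 (-0.63, adjusted p = 0.0958), Mbip (-0.59), Fgf17 (-0.53), the neuronal transcription factor Neurod1 (-0.51) and Maip1 (-0.17) were among those lower in stress. Each lay beyond the control mean in 6 of 6 stress rats and none passed.

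The thalamic marker list was lower in stress, and was the 1 list of 31 that camera called, with 6 at an unadjusted p under 0.05 (adjusted p = 0.0371; 0.924 with an estimated correlation). Its mean over 12 genes was 0.93 ± 0.43 in control and 0.58 ± 0.44 in stress (SD, n = 6 each), a difference of -0.35 that lay within the spread of the rats (exact permutation p = 0.184), with 5 of 6 stress rats below the control mean and fry p = 0.245. Without control 1, control 2, control 6, stress 2 or stress 4 the adjusted p was 0.154, 0.216, 0.0961, 0.307 or 0.288, so the call rests on each of these rats. With scan day as a block it was 0.140, and slide as a random block gave no call. Other settings lowered it, to 0.00841 with quantile normalization, 0.00470 with the slide set and 0.00265 with the slide set and scan day. Within slides 1 to 3 camera gave 0.00294. All of these are at the preset correlation, and with the slide set and the estimated correlation it was 0.948. The difference was 0.02 on day 1 (4 control and 2 stress rats, exact p = 1), -0.82 on day 2 (2 and 4 rats, exact p = 0.133) and -0.43 within slides 1 to 3 (exact p = 0.186).

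The striatal marker mean was 1.45 ± 0.04 in control and 1.59 ± 0.13 in stress (difference 0.13, exact permutation p = 0.0411, adjusted p = 0.429), higher than the control mean in 5 of 6 stress rats. The precursor marker Bmp4 and the hypothalamic neuron marker Lhx8 were higher in stress when adjusted over the list alone, and the cortical marker Neurod1 was lower, 1 gene in each of those lists. The other 12 cell and tissue lists had no gene past either adjustment, and for all 15 the count over all probes was 0.

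**Figure D2:**
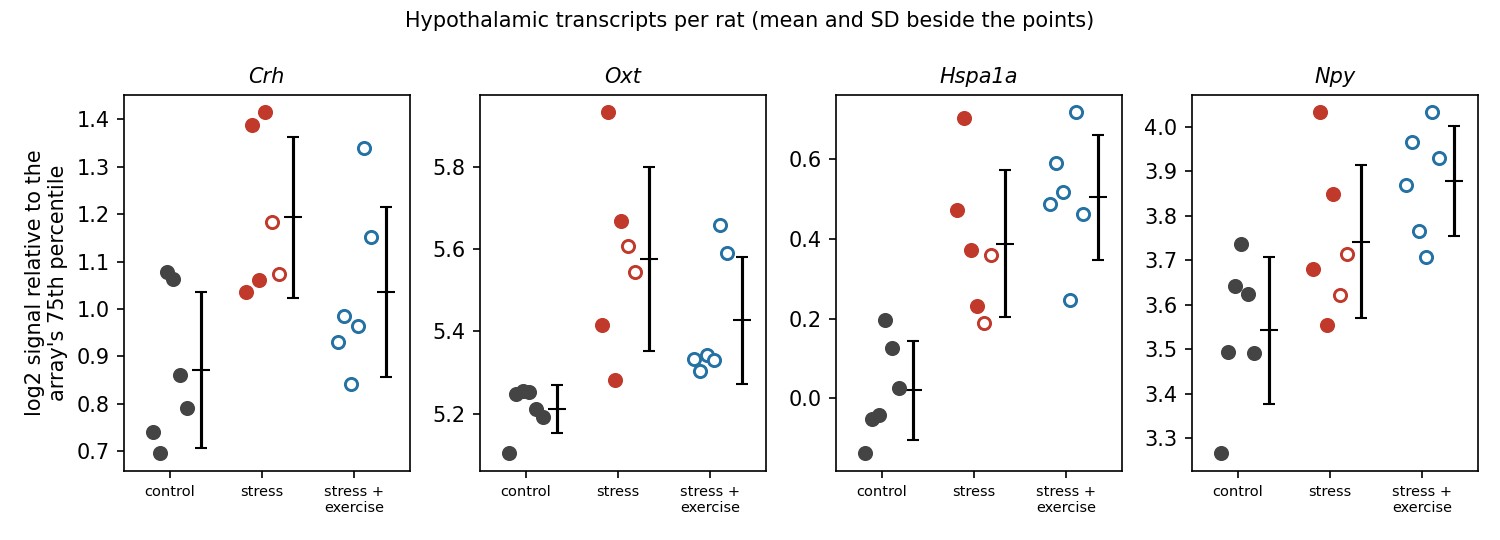
Levels of Crh, Oxt, Hspa1a and Npy (y axes, log2 relative to the array's 75th percentile) in each rat of the 3 groups (x axes); filled points lie on slides 1 to 3 and open points on slides 4 and 5, and bars give mean and SD over 6 rats. For Oxt, Crh and Hspa1a all 6 stress rats lie above the control mean, at adjusted p of 0.236, 0.273 and 0.236.

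Slide set and scan day bear on the stress count as well. Single slides cannot be parted from the group there, since none held both control and stress arrays. With the slide set as a covariate 1 probe without a gene name passed (-0.62, adjusted p = 0.0208), and within slides 1 to 3 limma called 0, with 2621 at an unadjusted p under 0.05. With scan day as a block 370 probes passed, while the count was 3274 within day 1, where the 2 stress rats were those of slide 4, and 0 within day 2, with 3688 at an unadjusted p under 0.05. Slide as a random block gave 0, with 2374 at an unadjusted p under 0.05.

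The comparison of stress with exercise against stress asks what the running wheel changed in restrained rats. The cytochrome oxidase gene Cox4i2 fell by 0.76 (SE 0.18) with exercise and Cox7c fell by 0.67 (SE 0.16), as did Id3, an inhibitor of transcription factor binding, by 1.51 (SE 0.33), and the angiotensin receptor gene Agtr1b by 1.16 (SE 0.29). The tyrosine kinase gene Srms rose by 0.56 (SE 0.10), the muscle-type myosin gene Myh7b by 0.49 (SE 0.08), the clock repressor gene Nr1d1 by 0.42 (SE 0.09) and the NMDA receptor subunit gene Grin1 by 0.30 (SE 0.07). These 8 genes lay beyond the stress mean in 6 of 6 exercised rats, with adjusted p between 0.0340 and 0.0420. With the slide set as a covariate none of the genes named by rule passed. Cox7c then differed by -0.04, Cox4i2 by -0.03 and Id3 by -0.26, whereas Srms differed by 0.55 and Myh7b by 0.32.

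In all, 1170 probes changed between stress with exercise and stress, 371 higher and 799 lower, and they held 508 gene names and 653 probes with none. Taken as 1 probe per gene, 209 of 13055 genes rose and 219 fell. Without scaling of the arrays, 2.40% of 1373 called probes were higher, against 31.7% at the main setting. Among the largest falls were Rpl27l2 (-1.72; another probe at 0.36), the acyltransferase gene Acnat2 (-1.45) and Cyp11a1, the enzyme that starts steroid synthesis (-1.41). The class I antigen gene RT1-CE5 was well above background in 4 of 6 stress rats and in 0 of 6 exercised rats. It was at least 1.97-fold lower with exercise (adjusted p = 0.0380). Its level was -4.25 to -4.08 in stress 1 to 4, -6.41 and -7.83 in stress 5 and 6, and -7.75 to -7.23 with exercise. The fall thus also parted stress rats without a wheel, along the slide set. Rises included the kinase gene Prkd2 (0.77), Fcna (0.51), the signalling gene Wnt7b (0.46), the neurofilament gene Nefh (0.44) and Maz (0.43).

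By function list, 6 of 89 genes with ribosomal protein symbols fell and 0 rose, among them Rpl17l5 (-0.61), Rpl22l1 (-0.23) and Rpl36al1 (-0.14). All 6 were among the 7 that passed when adjusted over the list alone, which also held Rpl27al1, Rpl27l2, Rpl39l5 and Rps19l3. Each has the symbol of a like gene, ending in l and a digit, and no main ribosomal protein gene passed. Another probe of Rpl22l1 was at -0.08 and did not pass (adjusted p = 0.477). Of 82 oxidative phosphorylation genes 3 fell (Cox4i2, Cox7c and Cox6c-ps1, by its symbol a pseudogene, -0.41) and 1 rose, the ATP synthase subunit Atp5f1d (0.19). Of 23 cholesterol synthesis genes 2 fell, Fdft1 (-0.35) and Idi1 (-0.17), and of 26 angiotensin and vascular genes 2 fell, with Agtr1b among them. Grin1 rose and the GABA receptor subunit Gabbr1 fell (-0.19; another probe at 0.10) among 25 glutamate and GABA genes. Nr1d1 was the 1 clock gene of 17 that rose, Sdf2l1 (0.23) the 1 of 21 heat shock and endoplasmic reticulum genes that rose, and RT1-CE5 the 1 of 28 interferon and antigen presentation genes that fell. In the other 8 function lists no gene passed over all probes. With camera 0 of 31 lists changed, with 9 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0520 for the interferon list (0.838 with an estimated correlation).

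Adjusted over the list alone, 7 genes of the ribosomal list, 7 of the oxidative phosphorylation list, 4 of the growth factor list (3 higher, Fndc5, Cntf and Syn1), 3 each of the feeding, angiotensin and vascular, and cholesterol lists, 2 each of the clock, heat shock, interferon and glutamate and GABA lists and 1 of the monoamine list passed. Over all probes these counts were 6, 4, 0, 0, 2, 2, 1, 1, 1, 2 and 0 in that order. The 3 of the feeding list include Sf1, which matched splicing factor 1 and is not a feeding gene. The stress axis, glucocorticoid, cytokine, immediate early and antioxidant lists had 0 genes under both adjustments by limma. The dopamine transporter gene Slc6a3 was at -4.20 ± 0.65 in stress and -2.42 ± 0.50 with exercise (difference 1.78, adjusted p = 0.0519), and the dopamine receptor gene Drd2 differed by 0.31 (adjusted p = 0.0799). Trh, the thyrotropin releasing hormone gene, differed by -0.27 (adjusted p = 0.0550) and the cytokine signalling inhibitor Socs3 by -0.36 (adjusted p = 0.0725), where another probe of Socs3 passed at -0.46 (adjusted p = 0.0430). None of the 10 genes named in every comparison passed by its brightest probe, with Crh at -0.16, Oxt at -0.15, Pomc at -0.24, Npy at 0.14, Fkbp5 at -0.19 and Fos at -0.21. Nr3c1 was at 0.03 by its brightest probe, and another of its probes passed at -0.26 (adjusted p = 0.0447).

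Of the cell and tissue lists, 1 gene rose in each of the microglial, mural, striatal and cortical lists and 1 astrocyte gene fell, and in the other 10 lists no gene passed over all probes. With adjustment over the list alone, 5 precursor markers passed (Cspg4, Olig1, Olig2, Enpp6 and Bcas1) and 4 mural ones (Pdgfrb, Rgs5, Abcc9 and Vtn). The same adjustment gave 4 striatal, 3 oligodendrocyte, 2 each of the astrocyte, pituitary and cortical lists and 1 each of the microglial, perivascular, ependymal and thalamic lists. It gave 0 of the endothelial, choroid plexus, hypothalamic neuron and erythrocyte lists. The monoamine list mean was -0.96 ± 0.05 in stress and -0.81 ± 0.07 with exercise, a difference of 0.14 that did not pass after adjustment (exact permutation p = 0.00433, adjusted p = 0.104), with 6 of 6 exercised rats above the stress mean. The striatal mean was 1.59 ± 0.13 in stress and 1.76 ± 0.19 with exercise (exact permutation p = 0.0931) and the thalamic mean 0.58 ± 0.44 and 0.94 ± 0.43 (exact permutation p = 0.171).

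**Figure D3:**
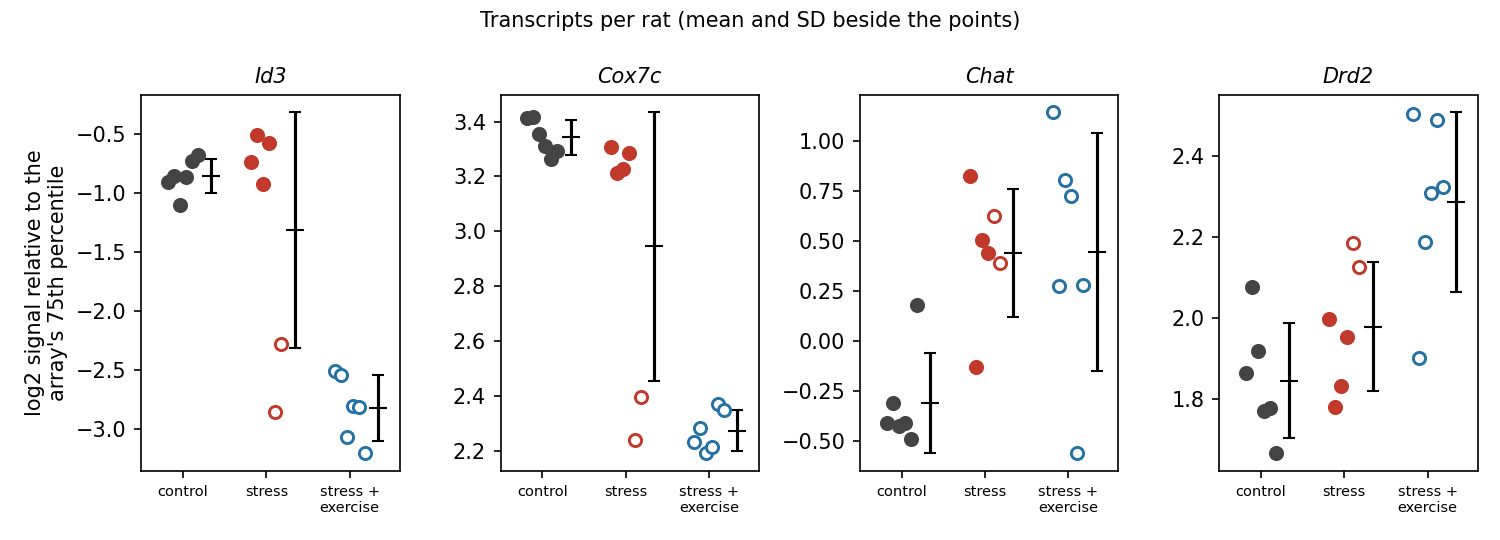
Levels of Id3, Cox7c, Chat and Drd2 (y axes, log2 relative to the array's 75th percentile) in each rat of the 3 groups (x axes); filled points are arrays of slides 1 to 3, open points those of slides 4 and 5, and bars give mean and SD over 6 rats. For Cox7c the 2 open stress points are at 2.24 and 2.40, beside the exercised rats (mean 2.27) and below the 4 filled stress points (3.21 to 3.31).

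The count depended on the slides and on single rats. Adding the slide set as a covariate left 5 probes, of which Kif16b, a kinesin gene (-2.59, adjusted p = 0.00012; -0.77 without the covariate), and the olfactory receptor gene Or5p66 (1.17, adjusted p = 0.0408; -0.56 without it) have names, given here after their values were seen. These probes of Kif16b and Or5p66 had mean levels of -3.99 and -5.02 over all arrays. The Kif16b probe is not the brightest of its gene, and the brightest did not pass. Within slides 4 and 5 alone (2 stress and 6 exercised rats) 3 passed, again with this Kif16b probe (adjusted p = 0.000326). Slide as a random block gave 0 (3431 at an unadjusted p under 0.05 by limma) and scan day as a block 3113. Day 2 alone gave 7091 (4 against 4 rats, slides 3 and 5) and day 1 alone, where all 4 arrays lay on slide 4, 0 (3303 at an unadjusted p under 0.05). A total of 1 to 4 probes passed without stress 1, stress 2, stress 3, stress 4, exercised rat 1, 2, 3, 4 or 6 or control 6, and 10 without exercised rat 5. The count was 43 without control 4, 164 without control 1, 222 without control 3, 257 without control 5 and 353 without control 2, but 4630 without stress 5 and 4383 without stress 6. The striatal and thalamic means as covariates left 1 probe.

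The comparison of stress with exercise against control joins both interventions. Chat, which encodes the enzyme that makes acetylcholine, rose by 0.75 (SE 0.23), the choline transporter gene Slc5a7 by 0.71 (SE 0.17), the vesicular protein gene Slc10a4 by 0.77 (SE 0.14) and the receptor gene Ngfr by 0.85 (SE 0.20). Stress rats, which had no wheel, were already at 0.44 ± 0.32 for Chat, against -0.31 ± 0.25 in control and 0.44 ± 0.59 with exercise, and their differences from control in Slc5a7, Slc10a4 and Ngfr were 0.56, 0.41 and 0.74, none of which passed. Cox7c fell by 1.07 (SE 0.16), Cox4i2 fell by 1.19 (SE 0.18) and Cyp11a1 fell by 1.92 (SE 0.37), and so did Agtr1b by 1.92 (SE 0.29) and Id3 by 1.97 (SE 0.33). Npy, the appetite-raising neuropeptide, rose from 3.54 ± 0.16 to 3.88 ± 0.12 (SD, n = 6 each; adjusted p = 0.00965) and Hspa1a by 0.48 (SE 0.09). All lay beyond the control mean in 6 of 6 exercised rats except Chat, in 5 of 6, with adjusted p from 0.000581 for Cox7c to 0.0210 for Chat. None of the genes named by rule passed with the slide set as a covariate, where Cox7c differed by -0.13, Id3 by -0.09 and Cyp11a1 by 0.13, but Slc10a4 by 0.73 (adjusted p = 0.398), Chat by 0.66 (0.691), Npy by 0.45 (0.410) and Hspa1a by 0.65 (0.273).

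In total 8506 probes changed, 4183 higher and 4323 lower, with 4106 gene names and 4069 probes without one. Counted as 1 probe per gene, 2365 genes rose and 1284 fell. Without scaling, 722 of 5170 called probes were higher, against 49.2% at the main setting. Among the genes named, Chat, the striatal adenosine receptor gene Adora2a, Bst2, Psmb8, Tef, Hspa5, Hmox1, Nfe2l2 and Htr2c then no longer passed. Further rises were in Qrfp, a feeding neuropeptide gene (0.72), Lhx8, a transcription factor of forebrain cholinergic neurons (0.69), and Adora2a (0.67; higher in 5 of 6 exercised rats). RT1-CE5, the connexin gene Gja3 and the olfactory receptor gene Or8b8 were not well above background in any exercised rat and were at least 4.56-fold, 4.25-fold and 3.63-fold lower there (adjusted p = 0.000579, 0.0103 and 0.000579); Gja3 was well above background in 5 of 6 control rats. Another probe of Gja3 was at -0.41 and did not pass (adjusted p = 0.269). The call for Adora2a was lost without control 3, control 5 or exercised rat 1, 3 or 4 (adjusted p 0.0501 to 0.0672).

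Over all 13055 genes tested, 2365 rose and 1284 fell, and the list counts that follow have to be read beside that share. Of 23 antioxidant genes 8 rose and 0 fell, among them Hmox1 (0.24), the regulator Nfe2l2 (0.23) and Gpx4 (0.22). When adjusted over the list alone, 9 passed. The list mean was 2.09 ± 0.02 in control and 2.19 ± 0.03 with exercise (exact permutation p = 0.00216, the smallest possible; adjusted p = 0.104), higher in 6 of 6 exercised rats, with fry p = 0.000162 and camera adjusted p = 0.234 (0.988 with an estimated correlation). Heat shock and endoplasmic reticulum genes numbered 5 that rose and 1 that fell of 21, including Hspa1a, Creld2 (0.34), Sdf2l1 (0.29) and the chaperone Hspa5 (0.15). Among 17 clock genes 5 rose and 1 fell, with Nr1d1 at 0.47, Dbp at 0.31 and Tef at 0.16. Cholesterol synthesis had 6 of 23 that rose and 3 that fell, with Fdft1 (-0.45) and Idi1 (-0.21) among the latter. The counts for these 3 lists were the same when adjusted over the list alone, 6, 6 and 9.

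Oxidative phosphorylation genes went both ways, 10 of 82 up and 9 down, as did ribosomal proteins, 9 of 89 up and 10 down, with Rpl17l5 at -0.90; 18 passed in each of these lists when adjusted over the list alone. Interferon and antigen presentation genes numbered 4 that rose, with Bst2 (0.31) and the immunoproteasome subunit Psmb8 (0.26), and 2 that fell. Angiotensin and vascular genes numbered 2 that rose, with the natriuretic peptide receptor Npr1 (0.28), and 3 that fell, with Agtr1b. In the stress axis list the PACAP receptor Adcyap1r1 rose (0.28) and Trh (-0.30) and the urocortin gene Ucn3 (-0.34) fell. Other probes of Adcyap1r1 were at 0.06 and 0.13 and did not pass (adjusted p = 0.754 and 0.492). Ucn3 no longer passed without control 3, 4 or 5 or exercised rat 1, 2 or 3 (adjusted p 0.0658 to 0.0871). Glutamate and GABA genes split 3 and 3, with Grin1 (0.42) and the GABA enzyme Gad2 (0.36) up and Gabbr1 (-0.30; another probe at 0.054) down. Monoamine genes split 1 and 1, with Drd2 (0.44) up and the serotonin receptor Htr2c (-0.15; another probe at 0.20) down. Growth factor genes numbered 3 up, with the synapsin gene Syn1 (0.26), and 2 down. Feeding genes split 2 and 2, glucocorticoid genes 3 and 1, cytokine genes 2 and 0 and immediate early genes 0 and 2. The feeding counts, here and adjusted over the list alone, include Sf1, which matched splicing factor 1 and is not a feeding gene.

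The counts adjusted over the list alone were 6 for interferon, 5 for angiotensin and vascular genes, 2 for the stress axis, 6 for glutamate and GABA, 2 for monoamines, 5 for growth factors, 4 for feeding, 1 for glucocorticoid, 0 for cytokine and 0 for immediate early genes. Of the 10 genes named in every comparison Npy alone passed at the main setting. Crh differed by 0.16, Oxt by 0.22, Avp by 0.16, Agrp by 0.25, Pomc by -0.04, Nr3c1 by -0.01, Fkbp5 by -0.15, Sgk1 by 0.02 and Fos by 0.10. Among the fits that left out 1 array, Oxt passed only without stress 2 (adjusted p = 0.0399). Of the genes other than Npy, 2 passed with normexp and quantile, 2 with only the 2 groups compared and 1 with array weights. Another probe of Nr3c1 passed at -0.55 (adjusted p = 0.000504).

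Striatal markers rose in 7 of 14 cases and fell in 0, with Drd2 and Adora2a among them (8 when adjusted over the list alone). Their mean went from 1.45 ± 0.04 in control to 1.76 ± 0.19 with exercise, above every control rat in 6 of 6 exercised rats. Its exact permutation p was 0.00216 (adjusted p = 0.0974; camera adjusted p = 0.163, 0.988 with an estimated correlation). Of 16 oligodendrocyte markers 5 rose and 0 fell (5 when adjusted over the list alone), and their mean went from 3.48 ± 0.07 to 3.61 ± 0.06 (exact permutation p = 0.00433, adjusted p = 0.0974), higher in 6 of 6 exercised rats. Rises and falls numbered 3 and 2 among 10 precursor markers, 3 and 3 among 18 endothelial, 1 and 2 among 20 microglial and 1 and 2 among 14 astrocyte markers. They were 1 and 1 among 15 mural and fibroblast, 1 and 1 among 14 ependymal and tanycyte and 1 and 1 among 16 hypothalamic neuron markers. Counts were 3 and 0 among 13 cortical, 1 and 0 among 12 thalamic, 0 and 2 among 7 pituitary, 0 and 1 among 13 choroid plexus, 0 and 1 among 10 perivascular macrophage and leukocyte and 0 and 1 among 7 erythrocyte markers. For these 13 lists the counts adjusted over the list alone were 5, 7, 3, 3, 1, 1 and 1, and then 3, 0, 2, 0, 1 and 1, in the orders given. By camera 0 of 31 lists changed, with 4 at an unadjusted p under 0.05. By fry 8 did, with adjusted p of 0.00433 for the antioxidant list, 0.00433 for striatum, 0.00596 for cortex and hippocampus, 0.0187 for pituitary (lower), 0.0293 for oligodendrocytes, 0.0332 for the clock, 0.0452 for heat shock and 0.0455 for precursors. By fry with the slide set as a covariate the p was 0.381, 0.144, 0.146, 0.0301, 0.344, 0.551, 0.0638 and 0.174 in the same order, and the pituitary list turned from lower to higher (median 0.33). None of these 8 passed the exact permutation test of list means after adjustment, the lowest adjusted p being 0.0974. The antioxidant and striatal means were at the smallest possible p of 0.00216, where a list alone cannot pass. For them this result therefore does not count against the fry calls. Fry gave 0 in the other 2 comparisons, with 7 and 0 at an unadjusted p under 0.05 for stress with exercise against stress and stress against control.

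**Figure D4:**
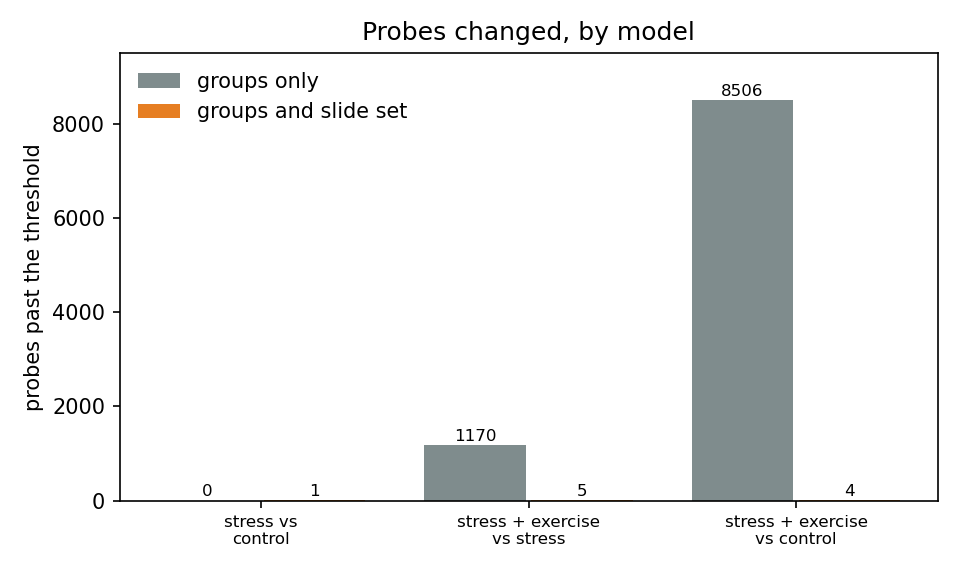
Bars give the number of probes past the threshold (y axis) in each of the 3 comparisons (x axis), for the fit with group alone and for the fit with the slide set added. The counts are 0, 1170 and 8506 with group alone and 1, 5 and 4 with the slide set, in the order stress against control, stress with exercise against stress, and stress with exercise against control.

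The slide set as a covariate left 4 probes, of which Kif16b (-2.83, adjusted p = 0.00102; -0.10 without it) and Or5p66 (1.52, adjusted p = 0.0343; -1.08 without it) have names, given here after their values were seen. Both are the same probes of low signal as against stress, and the brightest probe of Kif16b did not pass here either. Slide as a random block left 1644 probes, scan day as a block 10367, day 1 alone 4935 (4 control and 2 exercised rats) and day 2 alone 5621 (2 and 4 rats). With limma and the striatal and thalamic means as covariates 0 passed, with 6996 at an unadjusted p under 0.05.

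The direction of the exercise effect on stress genes was asked by correlating, across 13055 genes, the difference of stress from control with that of stress with exercise from stress. Genes are not independent replicates, so no p-value is given. With the 6 stress rats split so that the contrasts shared no array, the correlation averaged 0.31 over 20 ordered splits (SD 0.16, range 0.09 to 0.61), and unchanged simulated groups gave -0.01. A simulated slide effect with an SD of 0.3 log2 and no group effect gave 0.32. That SD was set by hand. For the 2 comparisons with exercise it gave 5774 and 13260 called probes on average, where the data gave 1170 and 8506. The layout of the slides can thus yield a positive value, of a size these data do not fix, and the correlation does not tell what running did. Genes such as Hspa1a (0.37 and then 0.12), Npy (0.20 and then 0.14) and Cox7c (-0.40 and then -0.67) had differences of 1 sign in both steps. Crh (0.32 and then -0.16) and Oxt (0.36 and then -0.15) had opposite signs, and of these differences only the Cox7c fall with exercise passed the test. Cox7c was at -0.08 and then -0.04 with the slide set as a covariate. With shared arrays the correlation was 0.11 and the covariance 0.00328, against -0.51 and -0.0101 in simulated unchanged groups, a difference of covariance of 0.0134. With stress against control taken within slides 1 to 3 and exercise against stress within slides 4 and 5, the correlation was 0.21. The slide set cancels there. Single slides and scan day do not, as in both steps the second group held more arrays of day 2, so this value does not decide either.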

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

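Every test in this part was chosen after the result it measures was seen, except the search for arrays far from their group.

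Of the 8506 probes that changed between control and stress with exercise, which share no slide set, 92.4% had the same direction between the stress arrays of slide 4 and those of slide 3, where the other 14 splits of the stress arrays gave 12.3% to 77.8%. Group with no difference between slides is argued against by the 3030 probes past the threshold between the stress arrays of slide 4 and slide 3. The other splits gave at most 1. These counts take only probes measured on all 6 stress arrays, and over all tested probes the first is 3040. An earlier test was the ratio of the fold with the slide set as a covariate to the fold without it. It had a median of 0.196 and quartiles of -0.0594 and 0.539 and did not decide. Transcript levels alone, from running or dissection, would give like folds from different probes of a gene, but folds from the brightest and second probe correlated at 0.245 over 851 genes (95% bootstrap interval 0.147 to 0.345), below the 0.481 to 0.616 of components 2 to 6, while differences between transcript forms stay open. What remains as a candidate explanation for most of these calls is something the arrays of slides 4 and 5 share, such as a labelling batch. Stress 5 and 6 had no wheel and show the pattern, so running alone does not account for it. Between them and the 6 exercised rats on those slides 3 probes passed, but that fit rests on 2 stress rats. In simulated data the fit with the slide set recovered 44.8% of changes of 0.5 log2 for stress with exercise against stress. The called probes had a median absolute difference of 0.285 log2, so effects of running as large as that stay open.

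The mean of the striatal list, higher with exercise than in control by 0.31, correlated when centred on each group with that of 7 cholinergic genes at 0.888 over 18 arrays (permutation p = 1e-05, the smallest the permutations can give), at 0.833 without the 2 farthest arrays and at 0.886 when centred on group and slide set. The cholinergic list, picked after the values were seen (Chat, Slc5a7, Slc18a3, Slc10a4, Ngfr, Gbx1 and Lhx8), had means of -1.19 ± 0.12 in control, -0.65 ± 0.26 in stress and -0.50 ± 0.37 with exercise, and all 7 of its genes and all 14 striatal ones were above background in control. The slide set cannot be told apart for the striatal list, since the mean of stress arrays was higher on slide 4 than on slide 3 by 0.0872 (exact p = 0.533) and 15 splits are too few to set a bound. Nor can it for the cholinergic list, whose mean was 0.50 higher in stress than in control within slides 1 to 3 (exact p = 0.0143), because 6 of its 7 genes are among the largest rises over the same control arrays and were picked with those values seen. More basal forebrain and striatum in the dissected piece may account for both lists, while an effect of restraint or running on these genes stays open and was not tested apart from it.

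The choroid plexus gene Ttr, which encodes the thyroxine carrier of cerebrospinal fluid, was at 6.78 in control 3, against 1.46 to 2.64 in the other controls, with a gap of 0.777 of the group's range. It was at 7.52 in stress 1. Of 12 other choroid plexus markers 5 (Folr1, Sostdc1, Aqp1, Kcne2 and Steap1) had their 2 highest arrays in the same pair, where 0.0784 would be by chance over 153 pairs of arrays. Choroid plexus in the dissected piece of these 2 rats is a candidate explanation, and the design gives no biological one to test.

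Other splits of the same arrays were tested for each count. For stress against control the real count was 0, which every split reaches (100 of 100, highest other 2), so splits say nothing there. For stress with exercise against stress, 4 of 100 splits gave at least the real 1166 of 31114 probes measured on all arrays, the highest other being 2406. All 4 were among the 6 drawn that keep the real imbalance of the slide set between the groups, and the splits with a smaller imbalance gave at most 6, which points to the slide structure of the arrays rather than to the group; with the slide set as a covariate 5 probes passed. For stress with exercise against control, 1 of 100 splits, the real one, gave 8463, and the highest other gave 76. The real split is the only 1 drawn that parts the slide sets fully, so a slide difference alone would rank it highest. This ranking therefore says nothing on the group apart from the slide set.

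Among 375 values tested for 1 array far from its group, 19 stood out, 11 in control, 6 in stress and 2 in stress with exercise, and chance gives about 1 in 20. The share of the group's range between the array and its nearest neighbour follows each name. High arrays were Avp in control 6 (0.628; 7.28), Chat in control 6 (0.729; 0.18), Glp1r in stress 2 (0.721; -5.00) and Msantd1 in stress 6 (0.627; -2.10). Low ones were Cox4i2 (0.663; 2.82) and Syn1 (0.669; 2.01) in control 5, Prkd2 (0.654; -4.65) and Qrfp (0.626; -4.11) in control 3, Fos in stress 5 (0.712; -3.57), and Mas1 (0.651; -4.56) and Slc5a7 (0.645; -1.28) in stress 2. List means stood out high for feeding in exercised rat 5 (0.635; -0.44), cholesterol synthesis in exercised rat 1 (0.795; 2.07), endothelium in control 2 (0.733; 0.38), cortex and hippocampus in control 1 (0.636; -2.43) and stress 6 (0.792; -2.57) and erythrocytes in control 5 (0.707; 2.17), and low for cholesterol synthesis in control 1 (0.868; 1.90).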

How the results depend on the processing

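The slide set, the slide set with scan day, slides 1 to 3 or 4 and 5 alone, and leaving out the 2 arrays with the highest Ttr were chosen after seeing the data; the other settings were planned. The cause was not tested for any change below unless it is given.

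Between stress and control the count of 0 probes became 2 with quantile normalization (1 of them Msantd1, 0.41, adjusted p = 0.0194), 1 with an intensity trend and robust fit, 6 at an adjusted p under 0.10 and 370 with scan day as a block. It was 1 with the slide set and 13 with the slide set and scan day. It stayed 0 with normexp and quantile, no scaling, the series matrix, no filter, the strict filter, 1 probe per gene, 2 groups alone, array weights, slide as a random block, dissection covariates, slides 1 to 3 alone and the Ttr arrays left out, by limma with 1723 to 4009 at an unadjusted p under 0.05. Leave-one-out gave 0 to 1, the 1 without control 1. With scan day as a block 9 of the genes named passed, B3gntl1 with the lowest adjusted p (0.00156), while Oxt (0.0668), Hspa1a (0.0587) and Crh (0.0931) did not.

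Between stress with exercise and stress the 1170 probes became 2365 with normexp and quantile, 3 without a filter and 537 with 1 probe per gene (fewer tested). It was 0 with the 2 groups alone (6598 at an unadjusted p under 0.05 by limma), 1983 with trend and robust fit, 7600 with array weights, 3673 at 0.10, 3113 with scan day as a block. It was 0 with slide as a random block (3431 at an unadjusted p under 0.05), 1 with dissection covariates, 5 with the slide set, 3 with the slide set and scan day, 3 within slides 4 and 5 and 1 without the Ttr arrays. Leave-one-out gave 1 to 4630. Quantile normalization, no scaling, the series matrix and the strict filter stayed within 1.5 times. The share higher was 2.40% without scaling, 23.8% with the series matrix and 52.3% with 1 probe per gene.

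Between stress with exercise and control the 8506 became 5170 without scaling, 3857 with 1 probe per gene, 1644 with slide as a random block, 0 with dissection covariates (6996 at an unadjusted p under 0.05 by limma), 4 with the slide set and 3 with the slide set and scan day. Leave-one-out gave 7389 to 8883, Oxt passed without stress 2 (0.22, adjusted p = 0.0399), and the other settings stayed within 1.5 times.

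With replicate number as a replicate block, which does not pair rats by any label, the counts were 0, 2 and 7319 in that order (3368 at an unadjusted p under 0.05 for the first), and 1 list moved between stress with exercise and stress (interferon, lower). In 18 pairs of arrays with the same number the residual correlation ran from -0.245 to 0.187, and 0 arrays correlated best with their own number.

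For lists, stress against control gave 1 at the main setting and 2 with normexp and quantile, 0 with scan day or slide as a block, 4 with dissection covariates, 0 with the estimated correlation, 3 with the slide set, 3 with the slide set and scan day, 2 within slides 1 to 3 and 4 without the Ttr arrays. Stress with exercise against stress gave 0, and 2 with quantile normalization, 4 without scaling, 3 with slide as a random block, 1 with dissection covariates, 9 with the slide set, 7 with the slide set and scan day, 8 within slides 4 and 5 and 1 without the Ttr arrays. Stress with exercise against control gave 0, and 1 without scaling, 1 with dissection covariates, 9 with the slide set and 4 with the slide set and scan day. With the slide set and the estimated correlation none passed (lowest adjusted p 0.948, 0.481 and 0.544 in this order). Leave-one-out gave 0 to 4, 0 to 4 and 0 to 1. The direction correlation of 0.31 was 0.38 with normexp and quantile, 0.29 with quantile normalization, 0.31 with the series matrix, 0.17 without a filter, 0.33 with the strict filter and 0.21 within slide sets.

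Some named genes changed sign. Between stress with exercise and control these were Adora2a with dissection covariates (-0.14), whose construction removes the striatal mean, Cyp11a1 (0.13) and Gpx4 (-0.0025) with the slide set, and Id3 (0.24), Cyp11a1 (0.17), Psmb8 (-0.012), Gpx4 (-0.075), Drd2 (-0.033) and Grin1 (-0.088) with the slide set and scan day. Between stress with exercise and stress it was Grin1 (-0.00413) with both covariates. Other probes differed in sign for Per1 (-0.14), Htr2c (0.05) and Nr3c1 (0.03) between stress and control, for Rpl27l2 (0.36), Gabbr1 (0.10) and Nr3c1 (-0.26) between stress with exercise and stress, and for Htr2c (0.20), Gabbr1 (0.054) and Nr3c1 (0.11) between stress with exercise and control. A part of the genes under the rule was followed across the settings, not all of them printed. These were 41 for stress with exercise against stress, of which 27 passed, and 51 against control, of which 42 passed. With the slide set none of these passed, and the direction was kept by all 27 and by 40 of the 42. Most of the fold was kept in that direction by only 9 of the 27 and by 26 of the 42. Genes under the rule outside this set were not counted here.

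Between 63.6% and 77.8% of probes were well above background, so genes dimmer than this are not covered.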

Other observations

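The tests in this part were chosen after the values were seen.

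With the slide set as a covariate, the comparison of stress with exercise against stress rests on stress 5 and 6 as the 2 stress rats of slides 4 and 5. In it camera at the preset correlation called the mural and fibroblast list higher (adjusted p = 2.53e-07), as well as microglia (0.00100), cytokines (0.00732), glucocorticoid-responsive genes (0.0173), endothelium (0.0173), growth factors (0.0277) and heat shock genes (0.0300). It called oxidative phosphorylation (0.00464) and cholesterol synthesis (0.0495) lower, but none passed with the estimated correlation (lowest adjusted p = 0.481). Within slides 4 and 5 the mural mean was 0.51 higher with exercise (exact p = 0.0714 over 28 arrangements), the pituitary mean 0.89 higher and the growth factor mean 0.15 higher (exact p = 0.0357 for both, the smallest possible). These p-values are not adjusted over the 31 lists and rest on 2 stress rats. The pituitary list includes Cga, which was at -6.52 and -5.50 in stress 5 and 6. The mural mean was at -1.59 and -1.76 in stress 5 and 6 and at -1.69 and -1.65 in control 3 and 4, and between -1.43 and -0.86 in the other 14 rats. Cga was low in those 4 rats too, but also in exercised rats 3 and 6, whose mural means were -1.36 and -1.43.

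Cga, the shared subunit of pituitary glycoprotein hormones, was not well above background in control 4 (-5.70), stress 5 (-6.52), stress 6 (-5.50) and exercised rat 3 (-5.50). It was at -4.03 in exercised rat 6 and -1.80 in control 3, and between 2.76 and 5.48 in the other arrays.

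Calls between stress with exercise and control differed by the kind of transcript a probe was designed on. Of called probes 33.2% were lower among those on curated coding transcripts, 87.4% among those on noncoding transcripts and 88.9% among those with a name only. The share was 61.7% on predicted coding transcripts, 54.5% on Ensembl transcripts and 62.9% on the remaining probes.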
